A study of Homo sapiens with 6 samples.

How the data were processed

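The series holds 6 one-colour Agilent SurePrint G3 human gene expression arrays hybridised with Cy3-labelled total RNA. Of these, 3 came from control U87 cells, titled wildtype, and 3 from U87 cells with RNA interference against AEP. The authors' spot intensity values were made with Agilent Feature Extraction 12.0.3.1, per the file headers, with 1 array per sample and no pooling. The processed intensity of a spot was background-subtracted and detrended, with surrogate values for low spots, and was not normalised between arrays, per the file headers. Raw spot intensity and local background intensity stood beside it, per the file headers. The authors also deposited a table of log2 values for the same arrays, log transformed and quantile normalised with limma, per the series description and the submitters' processing notes; the limma version is not given in the sources used here. The deposited log2 values had the same quartiles on every array, were not centred on genes, and were used as an alternative only.

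The main values here were log2 of the processed intensity, quantile normalised between the 6 arrays with limma 3.58.1 in R 4.3.3, because the submitters' notes describe that normalisation. Control spots were left out, as were 13 probes whose spots were marked as outliers, and spots of the same probe were averaged. A probe was tested where its spots lay well above background on all 3 arrays of at least 1 group, which left 34830 probes. No spot other than control spots was saturated. Of 58201 probes, 31104 were named by an accession in the reference table of GRCh38.p14, 3366 by a current symbol and 496 by an older symbol, while 21728 kept the name in the file and 1507 had none. The brightest tested probe stood for a gene, which gave 26102 genes; of 6032 genes with more than 1 tested probe, 826 (13.7%) had probes called in opposite directions. Probe coordinates are those of the files, on hg19 per the file headers, and the reference table served for names only. Exon and untranslated region annotation of that build was not used here.

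Knockdown was compared with control over all 6 arrays with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted over all genes tested), with group as the only term, 4 residual degrees of freedom and a threshold of 0.05. Changes are knockdown minus control on the log2 scale, with standard errors from the fit, and levels are means ± SD of normalised log2 values. LGMN was also tested with an exact two-sided permutation test. Where a gene was not well above background on any array of 1 group, its change is a lower bound, the mean of the bright group against, per array, the higher of the gene's own value and the lowest signal among probes well above background. The 29 gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. Lists with at least 5 measured genes were tested with camera in limma (preset inter-gene correlation of 0.01, two-sided, adjusted over the 29 lists), with camera under an estimated correlation, and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. Camera called 8 lists, 4 with an estimated correlation, and fry 28. The lists were p53 target genes, G1/S and DNA replication, G2/M and mitosis, apoptosis regulators, lysosome, autophagy, extracellular matrix and collagens, matrix proteases and inhibitors, integrins and adhesion, epithelial-mesenchymal transition factors, the mesenchymal glioblastoma subtype, neural progenitor and glial markers, interferon response, NF-kB and inflammatory cytokines, unfolded protein and ATF4 response, heat shock and chaperones, hypoxia and glycolysis, cholesterol synthesis and uptake, oxidative phosphorylation, ribosomal proteins, NRF2 targets, YAP and TEAD targets, immediate early genes, replication-dependent histones, and markers of myeloid, endothelial, neuronal, oligodendrocyte and epithelial cells.

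Named genes were LGMN, the 10 genes with the highest and the 10 with the lowest change among those past the threshold, without overlap between groups, well above background on all 6 arrays and with an established symbol, the 3 genes of each direction with the largest lower bound, and from each list up to 4 members with the smallest p (8 for the p53 list). Some genes that these rules pick are not reported here. Other genes are said where they appear to have been chosen after their values were seen. Alternatives were scaling to the 75th percentile, normexp background correction (offset 50), no background correction, no filter and a filter on all 6 arrays, the deposited log2 table, the median of a gene's probes, trend and robust variance estimates, array weights, the replicate number as a block, and leaving out each array in turn. A block for the slide could not be fitted, since each group lay in a scan of its own.

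The procedure was tested on simulated data with the control means and within-group spreads of the 26102 genes on 3 knockdown and 3 control arrays. It recovered 44% of 100 genes changed by 0.5 and 77% of 100 genes changed by 1 on the log2 scale, with 11 false calls. A shift of 0.5 in the p53 list was recovered and 0 of 29 lists were called without one. Simulated genes varied independently of each other, and far fewer were changed than in the data. Neither the gene results nor the list results of the simulation therefore give the power or the false calls of the tests on these arrays. Tables were handled with Python 3.11.15, pandas 2.3.3 and the R package data.table (version 1.17.8), and figures drawn with matplotlib 3.10.9. The series held no 2-colour data and no counts, and sequencing depth does not apply; the number of arrays limits the precision.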

Results

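Messenger RNA levels were measured in U87 cells, an established human glioblastoma line, on 6 one-colour Agilent arrays. On 3 arrays the RNA came from control cells, titled wildtype, and on 3 from cells in which asparagine endopeptidase had been reduced by RNA interference. The sample titles name no control construct, so effects of the interference procedure cannot be told apart from those of AEP loss. Asparagine endopeptidase (AEP, also called legumain) is a lysosomal cysteine protease that cleaves after asparagine residues and is encoded by LGMN. The series title names the tumour suppressor p53 as a protein that AEP inactivates in glioblastoma, so the comparison of knockdown with control cells bears on p53 target genes first and on the rest of the transcriptome after that. Each array carried 62976 spots. Of the 60901 that were not control spots, 59.2 to 59.9% lay well above background in the knockdown arrays against 62.1 to 64.2% in the control arrays. The 75th percentile of the processed signal was 220 to 237 in the knockdown arrays and 259 to 265 in the control arrays. Across genes, which are not independent replicates, Pearson's r between control arrays was 0.997 for each pair, between knockdown arrays 0.987 to 0.995, and between the groups 0.960 to 0.968. Knockdown replicate 1 stood furthest from its group, with r of 0.987 and 0.988. On 285 probes printed 10 times on each array, squared differences between control arrays were 0.959 to 1.27 times those expected from the scatter of repeated spots, and 1.39 to 8.08 times between knockdown arrays (1.35 to 3.33 times by the median over probes). The number of arrays limits the precision of every value below.

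LGMN, the target of the knockdown, was lower on every knockdown array. Its processed signal was 16.2, 20.7 and 14.7 in the knockdown and 267, 265 and 263 in the control. After normalisation its level was 4.23 ± 0.23 against 7.94 ± 0.02 on the log2 scale (SD, n = 3 arrays per group), which is 13.1-fold lower (log2 change -3.71, SE 0.12, adjusted p = 1.91e-05). The size depends on how the background under the low knockdown signal is treated, with a log2 change of -2.03 after normexp correction and -2.71 without background correction. An exact two-sided permutation test gave p = 0.1, the smallest p that 3 arrays against 3 can give. LGMN was read by 1 probe of 60 bases (A_23_P25994) that maps to chromosome 14, positions 93176171 to 93178016 of hg19, a stretch longer than the probe itself, so that the probe crosses a splice junction.

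Inflammatory cytokine genes made up 6 of the 10 largest rises among genes with an established symbol that were well above background on all 6 arrays. CXCL1, a chemokine that attracts neutrophils, rose 31.0-fold (log2 change 4.95, SE 0.06), CSF3, which encodes the granulocyte growth factor G-CSF, 25.7-fold (4.69, SE 0.07), and CSF2, which encodes GM-CSF, 18.3-fold (4.19, SE 0.04), each over n = 3 arrays per group. The cytokine gene IL1A (log2 change 4.07) and the chemokine genes CCL20 (3.91) and CXCL3 (3.91) were also among the 10 largest rises. So were SPRR2A (4.77) and SPRR2C (4.04), small proline-rich proteins of the epidermal cornified envelope, CADM1 (4.52), a cell adhesion molecule, and RDH16 (4.44), a retinol dehydrogenase. Second probes of CXCL1 and SPRR2A gave 3.93 and 2.97. SPRR2 genes are close copies of each other, as are CXCL1 and CXCL3, and a probe can bind the transcript of a near copy. The largest falls were those of DAPL1 (log2 change -6.28, SE 0.08, 77.9-fold lower), FOS (-4.72), an immediate early transcription factor, FOXS1 (-4.42), a forkhead transcription factor, and CLEC3B (-3.86), which encodes tetranectin. VHRT (-3.72), LGMN itself, the tubulin pseudogene TUBBP5 (-3.56), GAP43 (-3.48), a growth cone protein, HLA-DQA1 (-3.41), an antigen-presenting class II molecule, and CCN5 (-3.22), a matricellular protein, completed the 10 largest falls. The place of VHRT rests on 1 of its 2 probes, since the other gave -0.48. So does that of HLA-DQA1, whose other probe gave -2.69. DAPL1, CLEC3B, VHRT, TUBBP5 and HLA-DQA1 were dim in the knockdown, with mean log2 levels from 3.83 for HLA-DQA1 to 4.98 for TUBBP5. As for LGMN, the size of their falls may depend on the treatment of background. Adjusted p of these 20 genes ran from 3.45e-06 for CXCL1 to 5.79e-05 for VHRT.

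Some genes were well above background in 1 group only, and their change is given as a lower bound. RNF43, a ubiquitin ligase that restrains Wnt signalling, was at least 10.2-fold higher in the knockdown and SLIT2, an axon guidance ligand, at least 5.35-fold (adjusted p = 2.41e-05 and 9.27e-06). CRIM1, a transmembrane regulator of growth factors, was at least 8.67-fold lower in the knockdown, HLA-DQA2 at least 8.08-fold and CCN4, a Wnt-induced matricellular protein, at least 6.31-fold (adjusted p = 0.000568, 0.000501 and 1.44e-05). HLA-DQA2 and HLA-DQA1 are close copies, so their probes may share signal.

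**Figure D1:**
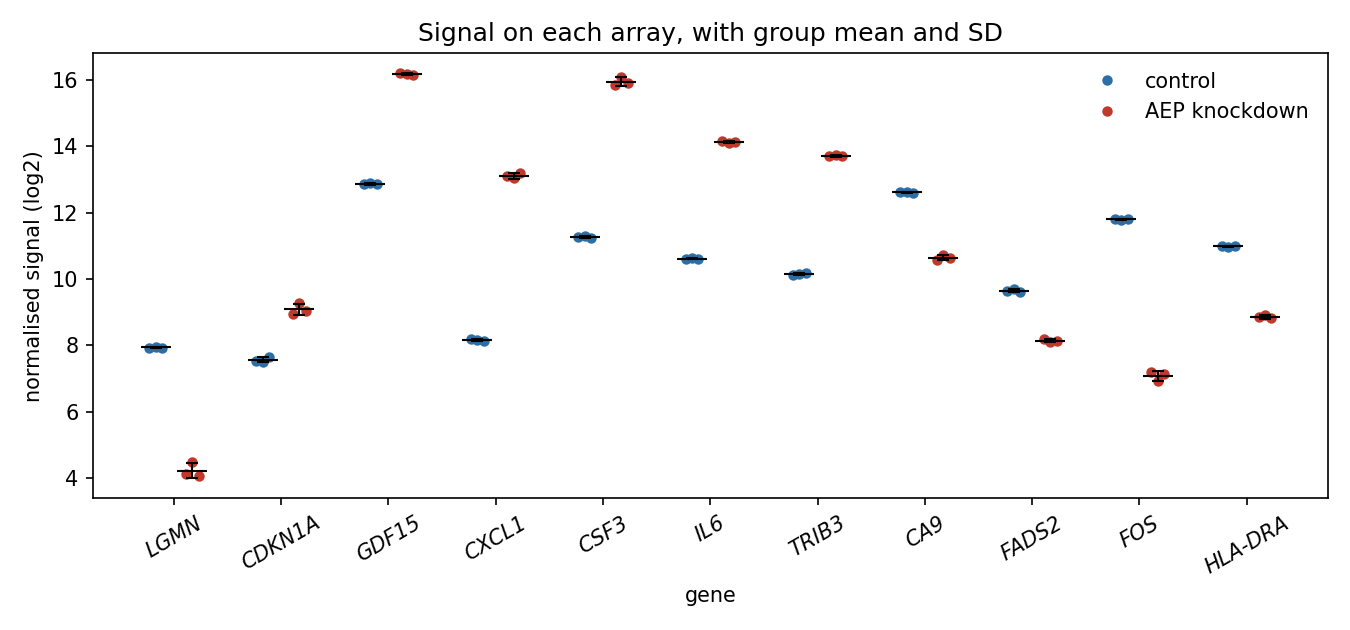
Normalised log2 signal (vertical axis) of 11 genes named in the text (horizontal axis) on each of the 3 control and 3 AEP knockdown arrays; points are arrays, black bars the group mean and SD. LGMN lies at 7.94 in the control and 4.23 in the knockdown, and the groups do not overlap for any of the genes shown.

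Of the 56 p53 target genes fixed for the comparison, all were measured; 32 rose, 18 fell and 6 did not pass the test (33 rose and 19 fell adjusted over the list alone). The largest rise was that of GDF15, a stress-induced secreted factor, at 9.91-fold (log2 change 3.31, SE 0.04, n = 3 arrays per group). SESN2 (1.86), a regulator of mTOR signalling under stress, GADD45A (1.84), a growth arrest and DNA damage gene, and LIF (1.75, and 0.81 by its other probe), a cytokine of the IL-6 family, followed. Among genes of cell death, PMAIP1 (1.53), which encodes NOXA, and TNFRSF10B (1.25), a death receptor for TRAIL, rose, as did the polo-like kinase gene PLK2 (1.39) and the lysosomal fucosidase gene FUCA1 (0.83). CDKN1A, which encodes the cell cycle inhibitor p21, rose by 1.52 (SE 0.10), MDM2, which encodes the ubiquitin ligase of p53, by 0.52 (SE 0.04), and BBC3, which encodes PUMA, by 0.73 (SE 0.06). TP53I3, a quinone oxidoreductase gene, fell by 0.50, ACER2, a ceramidase gene, fell by 0.81 and POLH, a translesion polymerase gene, fell by 0.55. CDKN1A, MDM2, BBC3, TP53I3, ACER2 and POLH were named after their values were seen. The median member stood at 0.30, and the list lay higher than the other genes (camera, adjusted p = 0.0200). This call was lost with an estimated correlation (camera, adjusted p = 0.102). The largest shift of spike-in transcripts between the groups was 0.34, and the list's median lay within it. The spike-ins were read with each array scaled to its 75th percentile, a scaling under which the list's median was 0.24. Past that shift, 20 members rose and 7 fell (limma's treat, chosen after the data were seen).

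**Figure D2:**
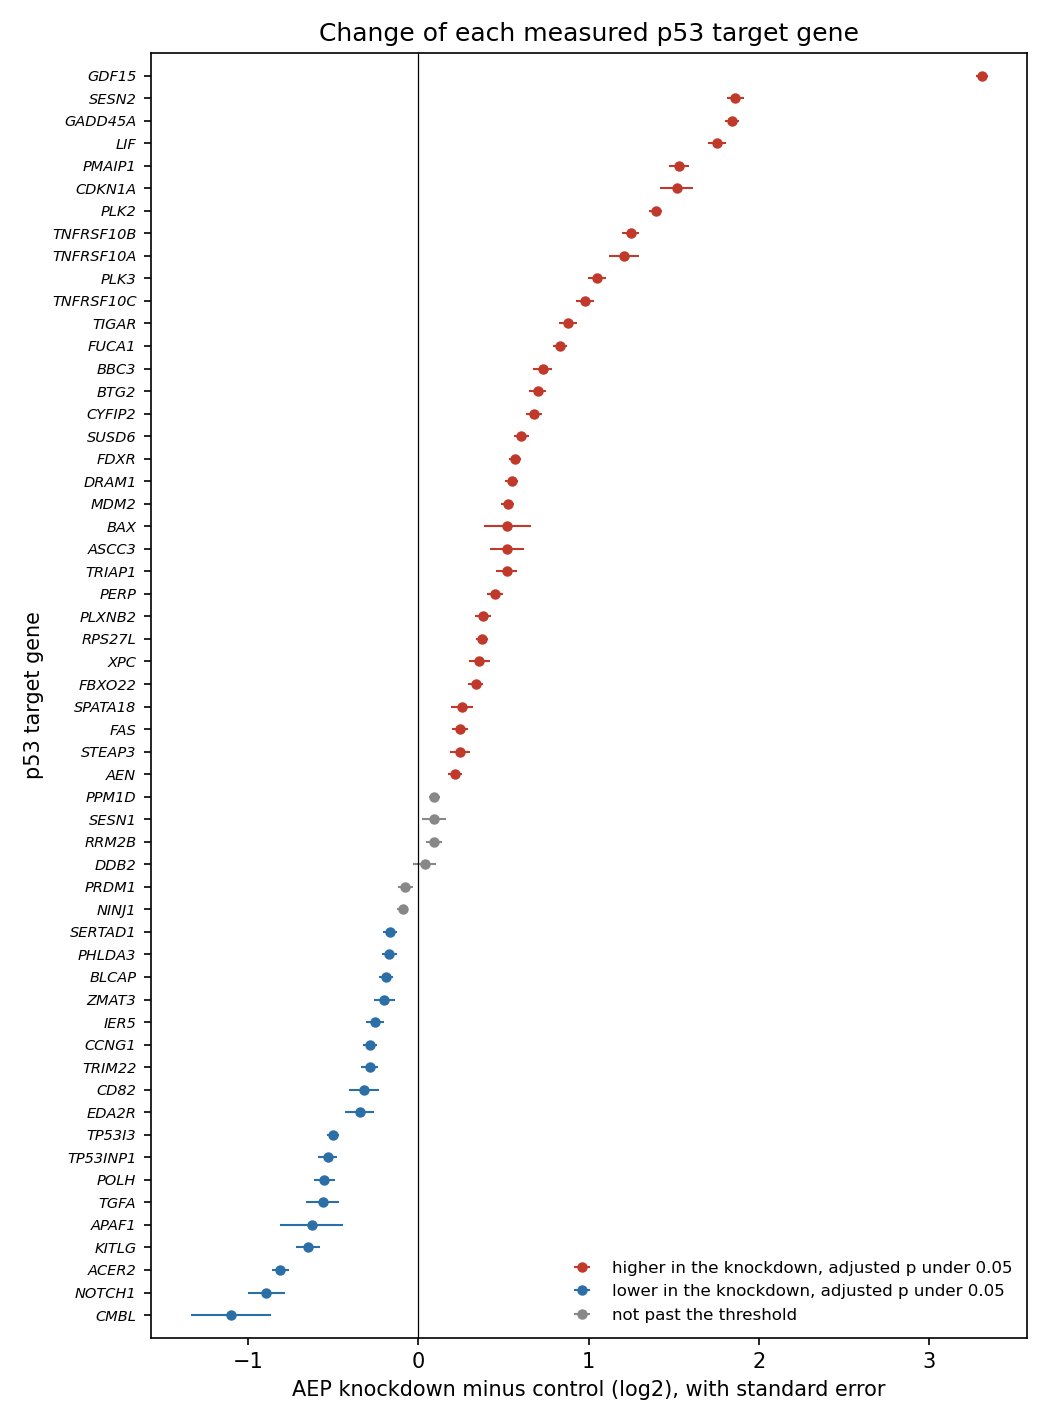
Log2 change, AEP knockdown minus control (horizontal axis), of each of the 56 p53 target genes (vertical axis), n = 3 arrays per group; points are the fitted changes, horizontal bars their standard errors, and colours the call at an adjusted p of 0.05. The 32 genes that rose run up to GDF15 at 3.31 and the 18 that fell run down to CMBL, drawn at -1.10, which was not well above background on any knockdown array.

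NF-kB targets and inflammatory cytokines rose almost throughout: of 33 measured members, 31 rose, 1 fell and 1 did not pass the test, with the same counts adjusted over the list alone. The median member rose by 1.49 on the log2 scale, and IL6, an inflammatory cytokine gene, rose 11.5-fold by its brighter probe (log2 change 3.52, SE 0.04, n = 3 arrays per group), while its other probe gave a log2 change of 0.83. The exceptions were IL11 (-0.09, adjusted p = 0.175) and BCL2A1, a survival gene of the BCL2 family (-0.13, adjusted p = 0.0410), both named after their values were seen. The BCL2A1 call was lost without knockdown replicate 2 or 3 or any 1 control array (adjusted p = 0.0696 to 0.113), and also with a replicate block (0.104), normexp (0.0664), no background correction (0.0945), no filter (0.0517) or the median of its probes (0.291). Genes of the unfolded protein and ATF4 response also rose, 28 of 38, with 6 lower and 4 not past the test (28 and 6 adjusted over the list alone; median 0.71). TRIB3, a pseudokinase induced under stress, rose 11.9-fold (log2 change 3.57, SE 0.04), CHAC1, which degrades glutathione, 6.18-fold (2.63), ASNS, asparagine synthetase, 4.13-fold (2.05), and the transcription factor gene ATF4 2.97-fold (1.57). Chaperones and folding enzymes of the endoplasmic reticulum moved both ways: PDIA6 (-0.98), PDIA4 (-0.71), HSP90B1 (-0.52), CALR (-0.32) and HSPA5 (-0.29) fell, while DNAJB9 (1.07), DNAJC3 (0.97), HYOU1 (0.59), DNAJB11 (0.58) and CANX (0.22, but -0.39 by the median of its 2 probes) rose. All were named after their values were seen. Against the other genes, the NF-kB list had an adjusted p of 1.02e-13 and the unfolded protein and ATF4 list one of 2.61e-06 (camera), and both calls held with an estimated correlation (adjusted p = 0.0399 for each).

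Genes of hypoxia and glycolysis fell: 30 of 35 were lower, 3 were higher and 2 did not pass the test, with the same counts adjusted over the list alone (median -0.53). PFKFB4, a regulator of glycolytic flux, fell by 2.11 on the log2 scale (SE 0.04, n = 3 arrays per group), CA9, a carbonic anhydrase induced by hypoxia, fell by 1.97, ANGPTL4, an inhibitor of lipoprotein lipase, fell by 1.83 and NDRG1, another gene induced by hypoxia, fell by 1.18. VEGFA (0.79), an angiogenic growth factor gene, DDIT4 (0.94), an inhibitor of mTOR signalling, and BNIP3L (1.28), a mitophagy receptor gene, rose by their brightest probe and were named after their values were seen. Of the 3 BNIP3L probes, called in opposite directions, the lowest gave -0.65, and the second VEGFA probe gave 0.19. Of 29 genes of cholesterol and lipid synthesis, 24 fell, 2 rose and 3 did not pass the test, likewise adjusted over the list alone (median -0.57). FADS2, a fatty acid desaturase, fell by 1.51 (SE 0.04), STARD4, a sterol carrier, fell by 1.16, and SQLE and NSDHL, enzymes of sterol synthesis, fell by 0.89 and 0.64. TM7SF2, a sterol reductase gene, was among those that rose (0.81) and was named after its value was seen. Adjusted p was 1.85e-07 for the hypoxia and glycolysis list and 1.05e-05 for the cholesterol list (camera), and both calls held with an estimated correlation (adjusted p = 0.0399 for each).

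Matrix genes, mitotic genes and lysosomal genes differed as lists from the other genes by camera under the preset correlation only. Of 45 genes of the extracellular matrix and collagens, 29 fell, 8 rose and 8 did not pass the test, with the same counts adjusted over the list alone (median -0.47). PLOD2 and P4HA2, collagen hydroxylases, fell by 1.67 (SE 0.04, n = 3 arrays per group) and 1.11, LAMA4, a laminin chain, fell by 1.56 (by as little as 0.15 on another of its probes), and LOXL1, a lysyl oxidase, fell by 1.28. DCN, which encodes the proteoglycan decorin (1.35), and FBLN5, which encodes fibulin 5 of elastic fibres (0.94), rose and were named after their values were seen. Of 45 genes of G2/M and mitosis, 29 fell, 4 rose and 12 did not pass the test (30 fell and 5 rose adjusted over the list alone, median -0.20). Only 7 of the mitotic genes fell and 1 rose past the largest spike-in shift, within which the median lay. RACGAP1, a regulator of cytokinesis, fell by 0.77 (SE 0.04), CDC20, an activator of the anaphase-promoting complex, fell by 0.71, and the mitotic kinesin genes KIF20A and KIF11 fell by 0.68 and 0.62. CDC25A (0.66), CCNA2 (0.34) and KIF2C (0.21) were among those that rose and were named after their values were seen. Of 56 lysosomal genes, 27 rose, 9 fell and 20 did not pass the test, likewise adjusted over the list alone (median 0.16). Past the largest spike-in shift, 15 lysosomal genes rose and 4 fell, and the median lay within that shift. ATP6V0A1, a subunit of the proton pump, rose by 0.95 (SE 0.03), and CSTB, the cathepsin inhibitor cystatin B, by 0.83. Adjusted p was 3.61e-05 for the matrix list, 0.00148 for the mitotic list and 0.0362 for the lysosomal list (camera), and these calls were lost with an estimated correlation (adjusted p = 0.0597, 0.0597 and 0.214 with an estimated correlation). The lysosomal call was also lost without control replicate 1 (adjusted p = 0.0584), with scaling to the 75th percentile (0.105), with the filter that asks for all 6 arrays (0.0944), with the median of a gene's probes (0.0986) and with a replicate block (0.0521).

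**Figure D3:**
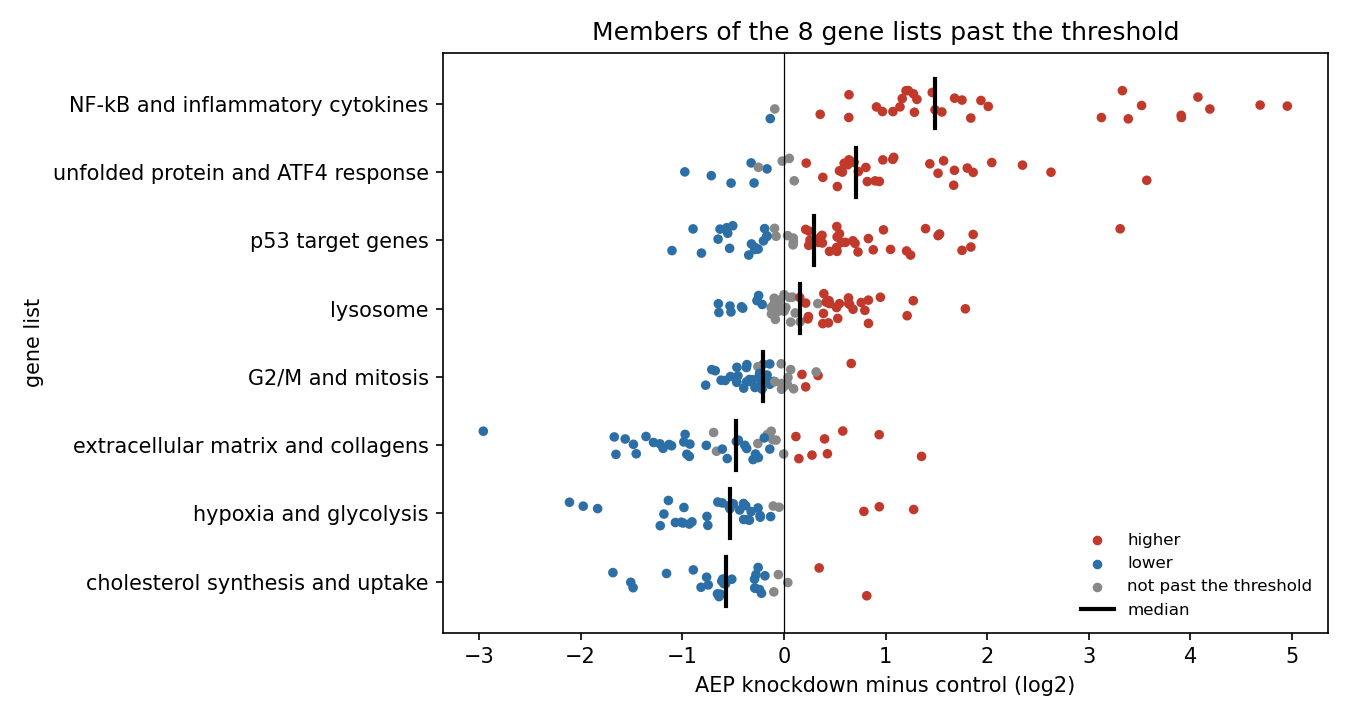
Log2 change, AEP knockdown minus control (horizontal axis), of each measured member of the 8 gene lists past the threshold (vertical axis), n = 3 arrays per group; points are genes coloured by their call, black bars are list medians. Medians run from -0.57 for cholesterol synthesis and uptake to 1.49 for NF-kB and inflammatory cytokines.

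The remaining 21 lists did not differ from the other genes by camera (adjusted p from 0.0958 for autophagy to 0.756 for matrix proteases). Oxidative phosphorylation and G1/S were called lower with scaling to the 75th percentile (adjusted p = 0.00179 and 0.0161) and without a filter (0.0247 and 0.0227), and autophagy was called higher without a filter (0.0494). Of 40 genes of G1/S and DNA replication, 5 rose and 19 fell, with the same counts adjusted over the list alone (3 and 18 without knockdown replicate 1). Past the largest spike-in shift, 0 of them rose and 5 fell. GINS1 (-1.09) and POLE2 (-0.55) were among the genes called lower. Of 39 apoptosis regulators, 18 rose and 13 fell (18 and 14 adjusted over the list alone), with HRK, a death activator of the BCL2 family, at 2.45. Of 35 autophagy genes, 16 rose and 8 fell (18 and 8 adjusted over the list alone), with GABARAPL1 at 1.07 and ULK1 at 0.66. Of 35 matrix proteases and inhibitors, 14 rose and 13 fell, likewise adjusted over the list alone; the collagenase gene MMP1 (2.13) and the stromelysin gene MMP3 (1.95) rose, while ADAM12 (-0.83, and from -1.25 to -0.32 over its probes) and TIMP2 (-0.81) fell. The median of that list was -0.06 and its mean 0.15, and its test pointed higher. Of 30 integrins and adhesion genes, 17 rose and 8 fell (17 and 9 adjusted over the list alone), with ICAM1 at 1.20 and ITGA10 at -2.14. Of 18 factors of epithelial-mesenchymal transition, 5 rose and 10 fell, likewise adjusted over the list alone, with TAGLN at 2.39, FN1 at -1.45 and SNAI2 at -0.72. Of 36 genes of the mesenchymal glioblastoma subtype, 12 rose and 20 fell (13 and 20 adjusted over the list alone), with CASP4 at 1.05 and CHI3L1 at -1.17. Of 43 interferon response genes, 12 rose and 17 fell (12 and 20 adjusted over the list alone), with STAT2 at 0.78, USP18 at -2.01 and IFIT1 at -1.60.

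Among housekeeping and stress lists, 12 of 24 heat shock genes and chaperones rose and 2 fell (11 and 2 adjusted over the list alone, and 12 and 4 without knockdown replicate 1). Past the largest spike-in shift, 2 of them rose and 1 fell. HSPA1B stood at 0.80 and CRYAB at -1.10. Of 46 genes of oxidative phosphorylation, 10 rose and 24 fell (11 and 24 adjusted over the list alone, and 0 and 8 past the largest spike-in shift), with ATP5F1B at -1.06 and SDHA at -0.83. Of 61 ribosomal protein genes, 21 rose and 11 fell (21 and 10 adjusted over the list alone, and 0 and 2 past the largest spike-in shift), with RPS19 at 0.40 and RPS12 at -0.57. The median of the ribosomal list was 0.04, and -0.11 with scaling to the 75th percentile (camera, adjusted p = 0.0385). Of 26 NRF2 targets, 16 rose and 6 fell, likewise adjusted over the list alone, with the cystine transporter gene SLC7A11 at 1.80 and TXNRD1 at 1.34. Of 23 YAP and TEAD targets, 12 rose and 8 fell, likewise adjusted over the list alone, with NUAK2 at 1.41, CCN1 at 1.05 and PTPN14 at -0.96 (-0.07 by another probe). Of 29 immediate early genes, 15 rose and 9 fell, likewise adjusted over the list alone; KLF4 (1.80) rose while FOS (-4.72), EGR1 (-1.59) and DUSP1 (-1.27) fell. The median of that list was 0.12 and its mean -0.07, and its test pointed higher. Of 36 replication-dependent histone genes, 11 rose and 10 fell, likewise adjusted over the list alone (0 and 2 past the largest spike-in shift). H4C4 stood at -1.17 (-0.02 by another probe) and H3C12 at -1.16, genes whose sequences resemble those of other histone genes.

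Markers of cell types were mostly dim and moved both ways. Of 16 markers of neural progenitors and glia, 3 rose and 9 fell, likewise adjusted over the list alone; the glutamate transporter gene SLC1A3 (-1.43, and -0.41 by another probe) and the progenitor marker NES (-1.47, and -0.52 by another probe) fell, and FABP7 was at least 3.26-fold lower. The median of that list was -0.57, or -0.45 with such genes at their bound. Of 10 measured myeloid and microglial markers, 2 rose and 5 fell, likewise adjusted over the list alone (2 and 3 without knockdown replicate 1), with CSF1R at -1.48, FCER1G at -1.32 (-0.76 by its other probe) and CD163 at 1.44. Of 8 endothelial markers, 2 rose and 5 fell (2 and 6 adjusted over the list alone), with ROBO4 at 1.19 and TEK at -0.88. Of 12 neuronal markers, 2 rose and 5 fell (2 and 6 adjusted over the list alone), with SNAP25 at -1.92 and TUBB3 at -1.03. Of 9 oligodendrocyte markers, 2 rose and 4 fell, likewise adjusted over the list alone, with CLDN11 at 1.28 and MAG at -0.84. Of 13 epithelial markers, 5 rose and 6 fell, likewise adjusted over the list alone (3 and 7 without knockdown replicate 1), with the keratin genes KRT18 at 1.68 and KRT8 at 0.70 and the serine protease gene ST14 at -0.94.

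Over all 26102 genes tested with limma, 16662 (63.8%) passed an adjusted p of 0.05, 8459 of them higher and 8203 lower in the knockdown, and 3786 of these changed by at least 2-fold, 1758 higher and 2028 lower. The balance depends on the setting: 7747 of 16763 called genes (46.2%) were higher with scaling to the 75th percentile and 47.9% without knockdown replicate 1, against 50.8% here. The groups did not overlap for 19152 genes (73.4%), where chance gives 10%. Of 15032 protein-coding genes, 5456 rose and 4845 fell. All 3 knockdown arrays were read in 1 scan and all 3 control arrays in another, so scan or slide and group cannot be told apart; 8 detected spike-in transcripts of a mix added to each RNA shifted between the groups by up to 0.34 on the log2 scale, and 7772 genes changed by more than that (limma's treat, chosen after the data were seen), LGMN among them. The spike-in shifts were taken with each array scaled to its 75th percentile, while treat and the list medians used quantile normalised values. The median change over all genes was -0.09 with that scaling and -0.04 with quantile normalisation. The limit of 0.34 is therefore approximate wherever it is set against quantile normalised changes. No label says that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

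**Figure D4:**
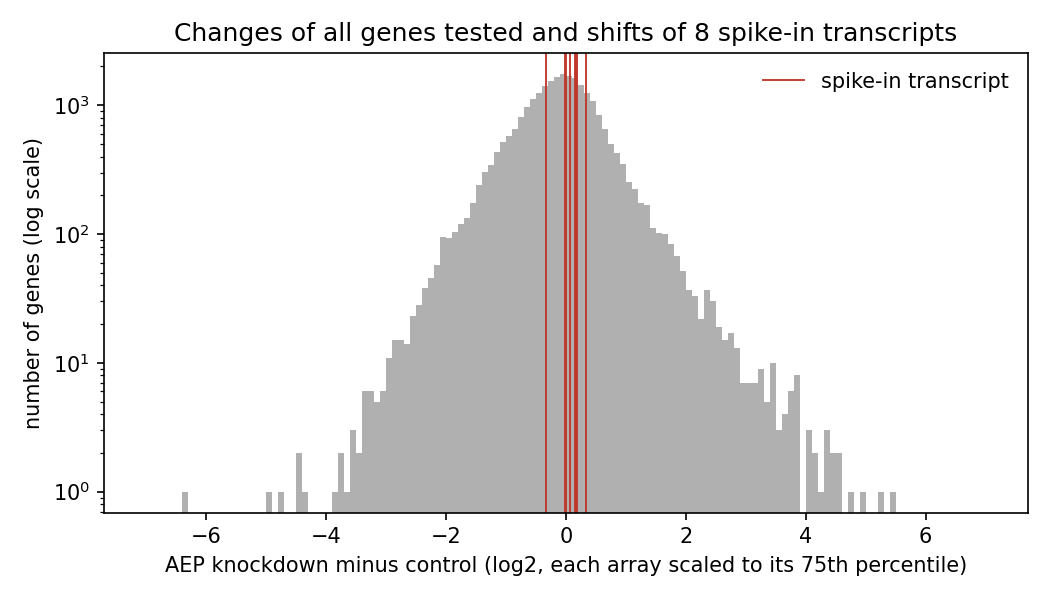
Number of genes (vertical axis, log scale) by log2 change, AEP knockdown minus control (horizontal axis), for all 26102 genes, with each array scaled to its 75th percentile; red lines mark the shifts of 8 detected spike-in transcripts on the same scale, n = 3 arrays per group. The spike-ins lie between -0.34 and 0.33, and genes extend well beyond them on both sides.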

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

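The tests on spike-in transcripts, on probe GC content and brightness and on the p53 list without shared members were chosen after the result was seen.

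Probes without a gene name were left out of the comparison of genes. Of 779 such probes well above background in at least 1 group, 175 were higher and 270 lower in the knockdown (limma, adjusted p under 0.05). Spike-in control spots were also outside that comparison, and the largest shift between the groups among the 8 that were detected was 0.34 on the log2 scale, for 1 transcript that was lower in the knockdown; 5 of the 8 did not overlap between groups.

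More than 60% of genes (16662 of 26102) differed between groups that lay in separate scans. A slide, scan or labelling difference as the whole cause is argued against by the spike-ins: 54.1% of 19847 genes of the same brightness range moved further than any of the 8 spike-ins, and at that share, if spike-ins moved independently of each other, the probability that none would move further is 0.00198. That range was wide, from 4.63 to 17.2 on the log2 scale, and genes were not matched to spike-ins within it. A spike-in value was the median over its spots, whereas only 300 other probes had repeated spots. The scatter of single spots may therefore raise the share of genes, and the probability is approximate. For changes no larger than 0.34, which are 3997 of the called genes (24.0%), such a difference and the knockdown cannot be told apart, because spike-ins moved as far. Removing a trend with probe GC content and brightness from each array left 16445 called genes, 15443 of them shared with the 16662, which argues against such a trend as the whole cause. The 10 splits of the 6 arrays cannot give a share under 0.05: 1 split, the real one, gave 16662 genes, and the highest of the others gave 0; a difference between the cultures other than the knockdown stays open and was not tested.

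The p53 target list lay higher in the knockdown, with 32 of 56 members up and 18 down (20 and 7 past the largest spike-in shift). The 44 members that stand in no other list had a median of 0.23 and a camera p of 0.0417. That p is not adjusted over the lists, and the unadjusted camera p of the full list was 0.0048. For oxidative phosphorylation, an unadjusted camera p of 0.043 became 0.104 on adjustment. The value therefore cannot decide whether members shared with other lists are the whole cause. The call was lost in the camera variant with an estimated correlation (adjusted p = 0.102). The estimate for this list was -0.0078, below the preset 0.01, so a higher correlation was not the reason. A greater p53 activity after AEP loss is a candidate explanation that these arrays, which hold no protein measurement, did not test, and the same genes respond to other stresses.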

How the results depend on the processing

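Thresholds at the largest spike-in shift, removal of the GC and brightness trend and the p53 list without shared members were chosen after the data were seen. The count of changed genes (16662) ran from 14323 to 17896 over other normalisations, filters, variance models and left-out arrays, and fell to 3786 when a 2-fold change was asked for and to 7772 with treat, both stricter by construction. LGMN stayed lower throughout, at -2.03 with normexp, -2.71 without background correction and -3.84 to -3.63 without each array in turn. The p53 list kept its call over other normalisations, filters, variance models and left-out arrays (camera, adjusted p = 0.0168 to 0.0262 without each array). It had 0.102 with an estimated correlation. Without shared members its camera p of 0.0417 was not adjusted over the lists. Of the lists, 7 to 11 passed in the other settings (7 to 8 without each array). With an estimated correlation 4 passed, and 28 with fry, which asks another question. Among lists lost, the estimate lay below the preset 0.01 for p53 (-0.0078) and mitosis (-0.0059), so a higher correlation was not the reason there. For the matrix and lysosomal lists the estimate was 0.011 and 0.014, little above the preset. The p also rose in lists that kept their call with an estimate below the preset. For hypoxia and glycolysis (-0.0049) the unadjusted camera p went from 1.28e-08 to 0.00275. For cholesterol (-0.0044) it went from 1.44e-06 to 0.00550. The loss of a call is therefore by itself no sign of a higher correlation, and its cause was not tested further. Same-numbered arrays of both groups did not deviate together (r of -0.09, -0.08 and -0.05), and no array correlated best with its own number; with a replicate block 14648 genes and 7 lists passed, and LGMN had an adjusted p of 0.00211. Reversed were the median of the ribosomal list (-0.11 with scaling to the 75th percentile), SDHD (0.18), RPL7 (0.16), RPS10 (0.0193) and CANX (-0.39) with the median of a gene's probes, and HLA-DOA (0.36) with the filter on all 6 arrays, where other probes were read by construction; the cause for the ribosomal list was not tested. Over 448 values of the other 28 lists, 437 were the same, 5 weaker and 5 stronger; over 2950 values of 185 named genes, 2908 were the same, 32 weaker, 5 stronger and 5 reversed. Dim genes are limited by signal over background.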

Other observations

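Chosen after the values were seen were the class II and ZNF-named genes with their list tests, the other genes outside the naming rule, the removal of the GC and brightness trend, and the weighing of the class II pattern; the interferon and myeloid lists and the other settings were fixed beforehand. The camera p-values of the class II and ZNF sets therefore describe sets picked from these same data and give no independent support.

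Genes of antigen presentation by HLA class II were lower in the knockdown. Of 15 measured class II genes (the pseudogene HLA-DPB2 aside), 14 fell (limma, adjusted p under 0.05), with a median of -1.47 (camera p = 2.79e-08, and p = 0.0143 with an estimated correlation). HLA-DRA fell by 2.13 (SE 0.04, n = 3 arrays per group), HLA-DQB1 fell by 2.33 (from -2.33 to -1.66 over its 5 probes), HLA-DMB fell by 1.96 and HLA-DPA1 fell by 1.40. HLA-DOB did not pass (0.26, adjusted p = 0.0533) but was called higher with a replicate block (0.0452), the filter on all 6 arrays (0.0434), array weights (0.0416), no background correction (0.0327) or without knockdown replicate 1 (0.0403). HLA-DOA, at -3.16, was well above background on only 2 of the 3 knockdown arrays and stood at 0.36 by another probe. CD74, the invariant chain that guides class II molecules, fell by 1.40 and CIITA, their main transcriptional activator, fell by 0.80 by its brighter probe, while its other probe gave -0.16. IRF1, a transcription factor of interferon signalling, rose by 1.22 and B2M, the light chain of class I molecules, by 0.45. The class I heavy chain genes did not rise with B2M: HLA-C fell by 0.21 (limma, adjusted p = 0.0105) and HLA-B did not pass (-0.12, adjusted p = 0.101).

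Genes named ZNF, most of which encode zinc finger transcription factors, were more often higher: of 375 measured, 208 rose and 60 fell, with a median of 0.25 (camera p = 3.29e-05, and p = 0.00638 with an estimated correlation). This median lay within the largest spike-in shift of 0.34. After removal of the trend with probe GC content and brightness, 212 rose and 58 fell, with a median of 0.27. SPRR2E (3.75) and SPRR2F (3.40) rose beside SPRR2A and SPRR2C, in a family of close copies. By chromosome, the median change of protein-coding genes ran from -0.08 on chromosome X to 0.12 on chromosome 18.

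Among myeloid markers, CSF1R fell by 1.48, FCER1G fell by 1.32 (its other probe gave -0.76) and CD163, 1 of 2 that rose, rose by 1.44, while PTPRC and TYROBP, which were dim, fell by 0.42 and fell by 0.69. The PTPRC call was lost without knockdown replicate 1 (adjusted p = 0.0712) or 3 (0.0894) or control replicate 1 (0.0896) or 3 (0.0946), with a replicate block (0.0905), without a filter (0.0544) and with the median of its probes (0.138). The TYROBP call was lost without knockdown replicate 1 (adjusted p = 0.0661) or 3 (0.0718) or control replicate 1 (0.0842), 2 (0.0695) or 3 (0.0680), with a replicate block (0.0519) and without a filter (0.0503).

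The class II pattern was set against 3 explanations. Myeloid cells among the control cells stay open, since the markers point both ways. Of the 17 fixed myeloid markers, 5 were well above background on all control arrays and lower in the knockdown (CSF1R, FCER1G, ITGAM, PTPRC and TYROBP). Against that, CD163 rose, CD14 stood at -0.04 and only 10 of the 17 were measured. A marker was measured only where it lay well above background on all 3 arrays of at least 1 group. Mean control levels were 5.11 for ITGAM, 5.28 for PTPRC and 6.13 for TYROBP, against a median of 10.26 for class II genes. Those of FCER1G (10.01) and CSF1R (12.13) lay near or above that median. Sequence shared among class II genes as the whole cause is argued against by CD74 (-1.40) and CIITA (-0.80, and -0.16 by its other probe), which do not resemble them, but how many of the 14 genes share signal was not tested. A lower interferon response stays open, since the interferon list was not called (camera adjusted p = 0.182) and its members moved both ways. No other biological explanation was tested, and each of the 14 genes moved further than the largest spike-in shift of 0.34.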
